A study of Homo sapiens with 3 samples.

How the data were processed

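The study mapped where the transcription factor FOXA2 sits on chromatin in Caco2, an established human colorectal adenocarcinoma cell line widely used as a model of the intestinal epithelium. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments held by a protein with an antibody and counts where their sequenced ends (tags) pile up. The labels describe 3 libraries, of which 2 are replicate FOXA2 immunoprecipitations and 1 is an input library of sonicated chromatin without antibody. A peak list was used for each replicate. The input entered only through the authors' peak calls, and its own values were not analysed here. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical.

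Reads were aligned to hg19, and the tools named are Bowtie 1.0.0 and HOMER 1.2, per the submitters' processing notes. Per the file headers, peaks were called with HOMER findPeaks in its factor style, separately in each replicate and against an input library. The replicates were not pooled. Each peak needed a 4-fold excess over input and over the surrounding 10000 bp, each with a Poisson p-value of 0.0001, at a false discovery rate of 0.001. The tag threshold at that rate was 11 in replicate 1 and 10 in replicate 2, per the file headers. A limit of at most 1 tag per base position was set for finding peaks. The assumed genome size was 2000000000 bp. The peak width was set by each library's fragment length, estimated at 88 bp in replicate 1 and 110 bp in replicate 2, so the lists hold peaks of a single width each, 123 bp and 151 bp as deposited. Peaks closer together than 244 bp in replicate 1, or 300 bp in replicate 2, could not be called separately.

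The deposited score of a peak is a whole number. Its sum over the list, multiplied by the library's total tags and divided by 10000000, was 0.45% above the header's number of tags in peaks for replicate 1 and 0.20% above it for replicate 2. It was therefore read as HOMER's tag count of the peak scaled by the authors to 10000000 tags per library and rounded, here called normalised tags. A score unit stands for 2.62 tags in replicate 1 and 1.58 tags in replicate 2. The score is the authors' own value and was used to rank peaks and to compare the replicates' values at the same site. It was turned back into approximate tags only to check the score, to estimate counting error and to test the effect of depth. The lowest scores, 3 and 5, stand for 7.85 and 7.88 tags, and with rounding for at most 9.16 and 8.67. These lie below the tag thresholds of the headers, so the score and the threshold do not rest on the same count. Nor does the score follow the limit of 1 tag per base position. The highest-ranked shared site stands for 1309 tags in a replicate 1 peak of 123 bp. Scores of the strongest peaks therefore include positions with more than 1 tag.

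From these lists, peaks were compared by overlap with bedtools 2.31.1, with at least 1 bp in common. A shared site is a replicate 1 peak that overlaps a replicate 2 peak, given at its replicate 1 coordinates. All coordinates are 1-based and on hg19. Chance overlap came from 1000 random placements of the replicate 2 peaks on their own chromosomes, within the span of the peaks found there, so assembly gaps were part of that span. The p-value is one-sided and cannot be lower than 0.001. Scores of shared and single-replicate peaks were compared by the difference in medians, with a two-sided permutation test of 100000 resamples, whose smallest p is 1e-05. Confidence intervals of shares are 95% Wilson intervals and cover counting error only. Peaks cluster along the genome and are not independent replicates, so every p-value here concerns positions or peaks and not the 2 libraries.

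The spacing of shared sites, their runs, the number of windows of 100 kb with 5 or more of them and their density per chromosome were analyses added once the lists had been examined. Spacing was compared with 1000 random placements and with 1000 random shifts of every site by 50 kb to 500 kb, which keep the regional density. Chromosome densities are per occupied Mb, meaning windows of 1 Mb that hold a peak of either replicate. Their 95% intervals, and those of the ratio of the replicates' peak numbers, come from 1000 bootstrap draws of the 1 Mb windows. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The overlap procedure was tested on simulated data. A list of 26907 peaks with 59.6% of its positions copied from replicate 1, moved by less than the overlap limit, gave an overlap of 59.9%. Of 100 random lists, each judged by fewer than 1000 placements, 1% reached a p of 0.05. Those lists were drawn by the same placement as the test, so this checks the computation and not the choice of random placement.

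The strongest shared sites and the densest windows named in the text follow a rule written before the data were examined: the 10 shared sites with the best mean rank of score over both replicates, and the 3 windows of 100 kb with the most shared sites. The peaks of a single replicate and the runs named were chosen from their values. The same plan held an annotation of sites by gene and transcript, forkhead and other motif counts, and a test of 15 gene lists. These were not analysed here, because no sequence or annotation on hg19 was used and the gene table at hand is on another assembly. For that reason no site is assigned to a gene. Alternatives were a reciprocal overlap of 50%, midpoints within 100 bp or 500 bp, the 13453 best-scored peaks of each replicate, other random placements, and, for spacing, windows and densities, the list of each replicate by itself.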

Results

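FOXA2, a forkhead transcription factor that can open compacted chromatin and is active in endoderm-derived tissues, was mapped by ChIP-seq in Caco2 intestinal epithelial cells to find the sites through which it could control their genes. The data comprise the peak lists of 2 replicate immunoprecipitations, each called against the input library. Replicate 1 held 26183147 tags and replicate 2 held 15756702. In replicate 1, 2284359 tags fell in peaks, which the authors' peak caller gave as an immunoprecipitation efficiency of 8.72%. In replicate 2, 813811 tags fell in peaks, an efficiency of 5.16%. Since the design holds a single cell line and condition, the comparison it allows is between the replicates.

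FOXA2 occupied many positions, and those found in the smaller list were nearly all in the larger one. Replicate 1 held 63949 peaks and replicate 2 held 26907, so replicate 1 had 2.38 times as many peaks from 1.66 times as many tags. Of the replicate 2 peaks, 24344 overlapped a replicate 1 peak, which is 90.5% (95% Wilson interval 90.1% to 90.8%). Random placement of the same peaks gave an overlap of 0.621% ± 0.0487 (mean ± SD of 1000 placements) and never more than 0.766% (one-sided permutation p = 0.001, the smallest these placements can give). Seen from replicate 1, 24345 peaks were shared, or 38.1% (37.7% to 38.4%), and 39604 were found in that replicate alone. The centres of overlapping peaks lay a median of 15 bp apart, and 90% of them lay within 47 bp. The peak caller had discarded 12058 of 79191 putative peaks in replicate 1 and 3854 of 31642 in replicate 2 for too little excess over input, or 15.2% and 12.2%.

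Sites shared by the replicates were the higher-scoring ones. In replicate 1, the median score of shared peaks was 16 normalised tags (interquartile range 10 to 28), against 6 (5 to 8) for peaks absent from replicate 2 (two-sided permutation p = 1e-05, the smallest 100000 resamples can give). In replicate 2, the median was 13 (8 to 22) for shared peaks and 8 (7 to 11) for the others (two-sided permutation p = 1e-05). A shared peak has to pass the calling threshold of both replicates, so the direction of these differences follows in part from the calling. Among the 10% of replicate 1 peaks with the highest scores, 97.8% were shared (95% Wilson interval 97.4% to 98.1%). The shared percentage was 46% where the median score was 11, and 4.04% in the 10% of peaks with the lowest scores. In replicate 2 it changed less, from 96.7% in the 10% with the highest scores to 76.2% in the 10% with the lowest. Shared sites carried 67.4% of the summed score of replicate 1 and 92.3% of that of replicate 2. Peaks found in replicate 1 alone are thus mostly weak ones, and their absence from replicate 2 is not by itself evidence of absent binding.

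**Figure D1:**
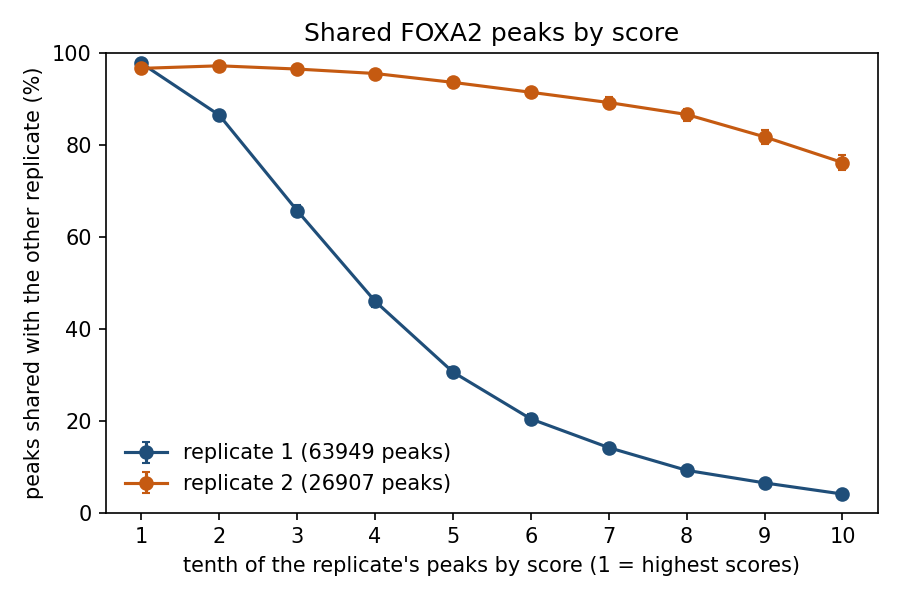
Percentage of each replicate's peaks that overlap a peak of the other replicate, in 10 equal groups of the peaks ranked by score. Points are percentages and bars are 95% Wilson intervals. Replicate 1 falls from 97.8% to 4.04% and replicate 2 from 96.7% to 76.2%.

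At shared sites the scores of the replicates rose together. Across 24345 sites, Spearman's rho was 0.78 and Pearson's r of the log2 scores was 0.83. These are correlations across sites, which are not independent replicates, and no p-value is given. The median of the ratios of replicate 1 to replicate 2 at the same site was 1.20, a log2 ratio of 0.26. This ratio is approximate, since peaks were 123 bp wide in replicate 1 and 151 bp in replicate 2, and each had to pass its own threshold. The log2 ratio varied between sites with an SD of 0.62, and 2378 sites, or 9.77%, differed by more than 2-fold from the median ratio. The spread was smaller over sites that scored high in both replicates. The SD was 0.46 over the 6271 sites that scored at least 20 in both replicates and 0.31 over the 267 sites that scored at least 100. The SD estimated from counting error was 0.41 over all shared sites, and 0.24 and 0.12 over these sets. Part of the fall in spread is therefore a fall in counting error. A limit on both scores also removes sites that scored high in a single replicate, which narrows the spread by selection. The 2434 shared sites with the best mean rank, 10% of them, held 34.0% of the shared sites' summed score in replicate 1 and 34.5% in replicate 2.

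**Figure D2:**
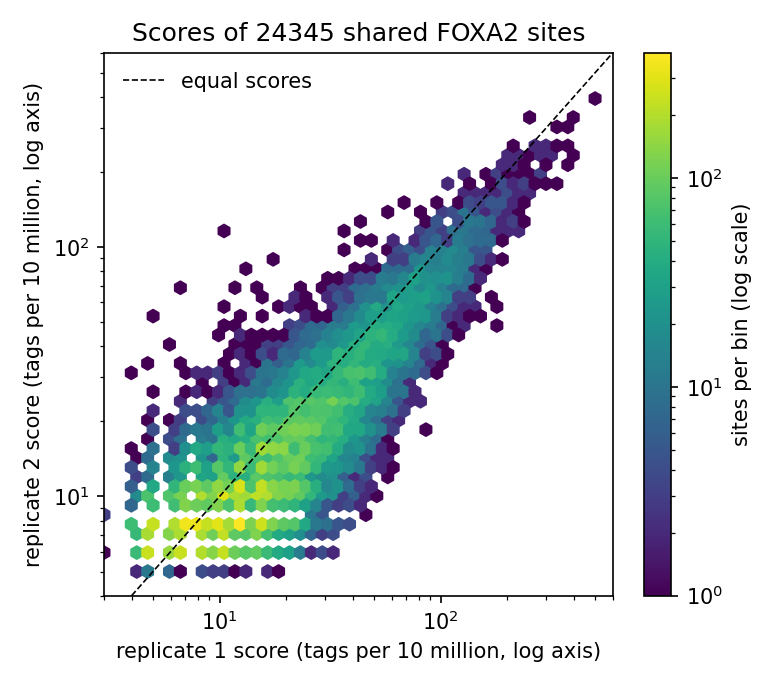
Scores of the 24345 shared sites in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), in normalised tags. Colour gives the number of sites per bin on a log scale, and the dashed line marks equal scores. Most sites lie near or to the right of the line, with a median ratio of 1.20.

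The shared site with the best mean rank of score lay on chromosome 10 at 60228467 to 60228589, with a score of 447 ± 75 (mean ± SD, n = 2). It scored 500 in replicate 1 and 394 in replicate 2, which is 62.5 and 35.8 times the median peak of each list. The next was on chromosome 5 at 19880983 to 19881105, with 372 ± 38.2. Chromosome 6 held the site at 106795219 to 106795341, with 349.5 ± 64.3, and the site at 109225167 to 109225289, with 319 ± 39.6. The site on chromosome 12 at 24907752 to 24907874 scored 324 ± 117 and had the widest spread of the 10, with 407 in replicate 1 and 241 in replicate 2. Chromosome 15 held a pair of them, at 69887099 to 69887221 with 318 ± 86.3 and at 70432958 to 70433080 with 278 ± 25.5. The remaining sites lay on chromosome 11 at 116679078 to 116679200 (299 ± 56.6), on chromosome 2 at 158913592 to 158913714 (283.5 ± 62.9) and on chromosome 5 at 123997392 to 123997514 (278.5 ± 33.2), each with n = 2. All 10 scored higher in replicate 1, by 1.14 to 1.69 times. The centres called in the replicates differed by at most 22 bp at any of them. These sites were not all isolated: the nearest other shared site lay 0.87 kb from the chromosome 5 site at 123997392 and 1.01 kb from the chromosome 6 site at 109225167, but 39.0 kb from the chromosome 2 site.

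Shared FOXA2 sites lay in groups. Of the 24345 sites, 9489 had another within 10 kb, which is 39.0%, against 15.9% on average and 16.9% at most in 1000 random placements (one-sided permutation p = 0.001). Random shifts of 50 kb to 500 kb, which keep the regional density, gave 23% on average and 24.1% at most (p = 0.001, one-sided permutation). Sites with such a neighbour had a median mean score of 16 (interquartile range 10.5 to 27.5), against 13.5 (9.5 to 23) for the 14856 sites without one (two-sided permutation p = 1e-05). The difference was 1 unit in replicate 1 and 3 units in replicate 2. In all, 822 windows of 100 kb held 5 or more shared sites and together 20.1% of them. Random placements gave 62.9 such windows on average and 92 at most (one-sided permutation p = 0.001). The number of such windows was not compared with shifts that keep the regional density, which may account for part of this excess.

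On the grid used, the window with the most shared sites was on chromosome 2 from 151000001 to 151100000 and held 13 of them over 78.0 kb. Its strongest site, at 151071271 to 151071393, scored 117.5 ± 2.12 (SD, n = 2), and the other 12 had mean scores between 8.5 and 32.5. On chromosome 11, the window from 20000001 to 20100000 held 12 shared sites, with the strongest at 20052723 to 20052845 (97 ± 28.3, n = 2). On chromosome 2, the window from 43200001 to 43300000 also held 12, with the strongest at 43206843 to 43206965 (122 ± 4.24, n = 2). Each of the 3 windows thus combined a strong site with many of moderate or low score. Random placements never put more than 10 sites in a window. Shifts that keep the regional density reached 15, so the counts of these single windows did not exceed that range. Their order also depended on the grid: moved by 50 kb, it gave 10 sites for the first window and 12 for each of the others. With midpoints within 500 bp, the first and the last held 13 each.

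**Figure D3:**
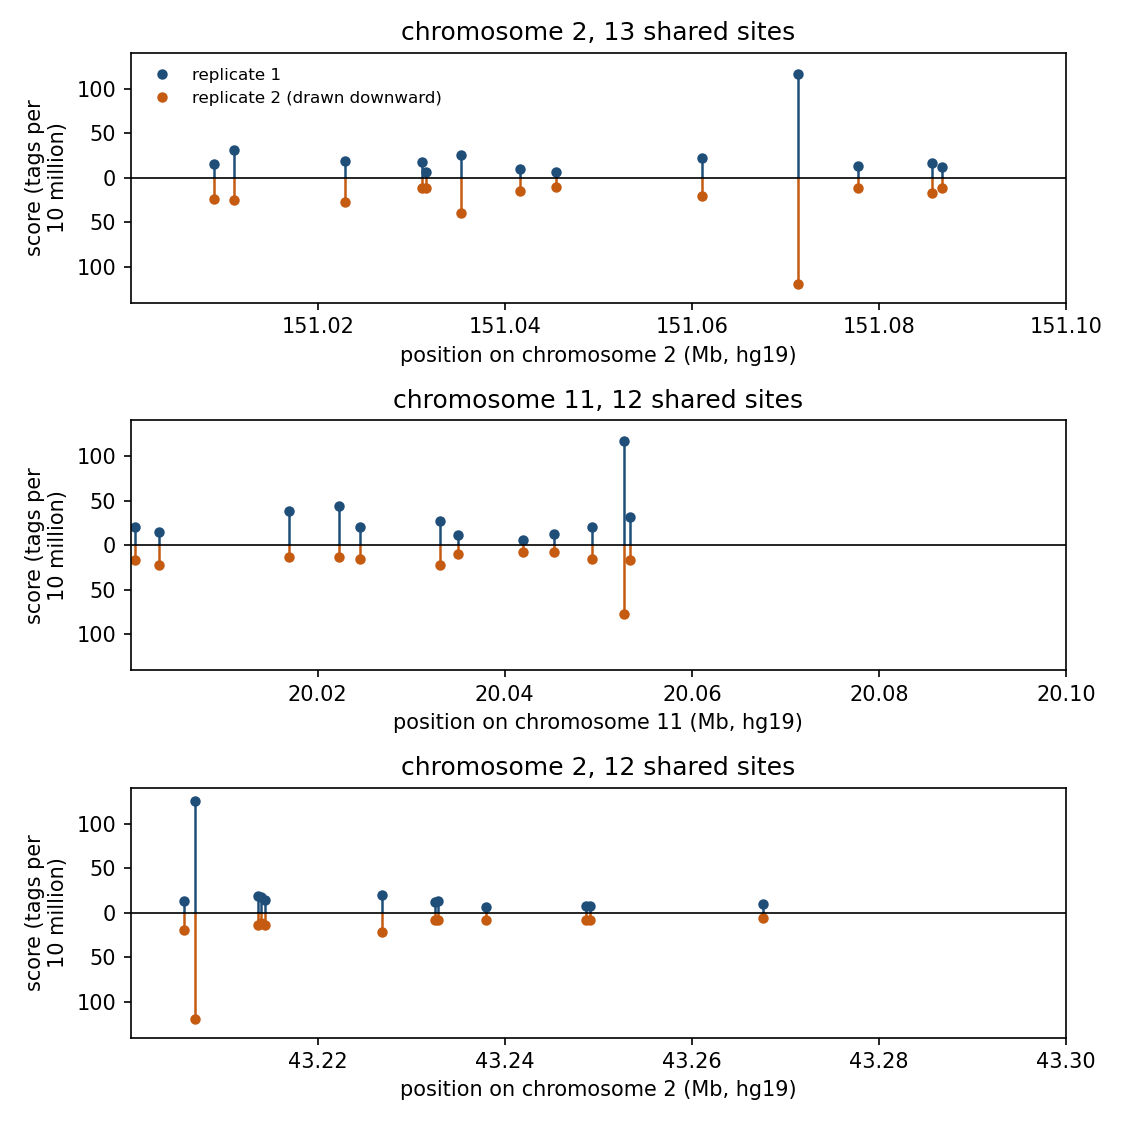
Shared FOXA2 sites in the 3 windows of 100 kb that held the most of them, with position on hg19 in Mb on the horizontal axis and the score in normalised tags on the vertical axis. Replicate 1 is drawn upward and replicate 2 downward. In each window a single site scores near or above 100 in replicate 1 (116, 117 and 125) and the others score less.

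FOXA2 sites were unevenly spread over the chromosomes. Over the genome there were 8.59 shared sites per occupied Mb. Chromosome 11 had the highest density, 12.2 per Mb (95% bootstrap interval 10.7 to 13.7), followed by chromosome 2 with 10.1 (9.19 to 11.2). Chromosome X had 4.0 (3.34 to 4.63) and chromosome 19 had 5.61 (4.39 to 6.79). Of 23 chromosomes (1 to 22 and X), 3 lay above the genome's density with their whole interval and 8 below it, where about 1.15 would be expected by chance. These densities are not corrected for the copy number of each chromosome, which is altered in Caco2 cells. The replicates did not hold the chromosomes in equal proportion. The ratio of replicate 1 to replicate 2 peaks was 2.85 on chromosome 19 (2.57 to 3.21), 2.81 on chromosome 20 (2.61 to 3.05) and 2.68 on chromosome 22 (2.43 to 3.05), against 2.22 on chromosome 4 (2.10 to 2.34). Chromosome Y was left out of these counts and of the plot. It held 1 peak in replicate 1 and 24 in replicate 2, a ratio of 0.0417 that runs the other way, and these peaks are part of the genome's ratio. Among the other 23, for 7 chromosomes the interval left out the genome's ratio of 2.38, with 5 above it and 2 below it.

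**Figure D4:**
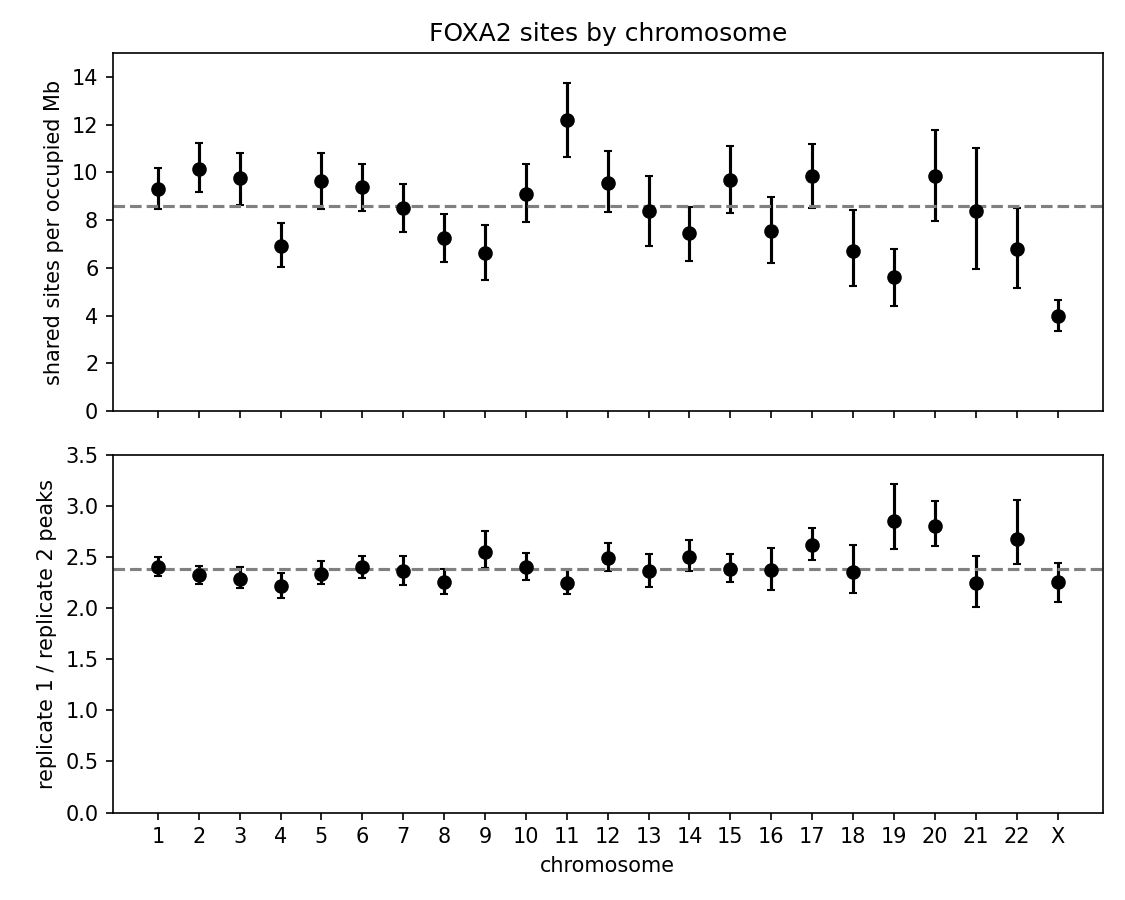
Shared FOXA2 sites per occupied Mb (upper plot) and the ratio of replicate 1 to replicate 2 peak numbers (lower plot) for chromosomes 1 to 22 and X. Points are values, bars are 95% bootstrap intervals over windows of 1 Mb, and dashed lines are the genome's values of 8.59 and 2.38. Chromosome 11 is highest in density, X is lowest, and chromosomes 19 and 20 have the highest ratios.

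A few strong peaks were found in a single replicate. With 500 bp allowed between centres, 46 peaks that scored at least 50 in replicate 2 had no counterpart in replicate 1, against 1674 that did. The highest of them were on chromosome 1 at 121485102 to 121485252, with a score of 7971, and on chromosome 10 at 42392657 to 42392807, with 732. Of these 46 peaks, 34 lay within 1 Mb of a stretch of at least 1 Mb without peaks of either replicate. Whether such peaks mark FOXA2 binding stays open, as set out under the other observations. In replicate 1 a single peak of at least 50 had no counterpart, the one on chromosome 11 at 85195039 to 85195161. Its score of 570 was the highest of that list. This contrast depends on the limit: at a score of at least 20, 357 replicate 1 peaks and 136 replicate 2 peaks had no counterpart.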

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

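All 20 alternatives of the overlap, score and spacing results kept their direction and side of the threshold. The 15 of the window counts, which have no test, stayed within 1.5 times. The percentage of replicate 2 peaks shared with replicate 1 was 85.7% with a reciprocal overlap of 50%, 89.5% with midpoints within 100 bp and 92.8% with midpoints within 500 bp. It was 75.3% when the 13453 best-scored peaks of each replicate were compared, where the shorter list of replicate 1 removes partners by construction. The chance level moved from 0.621% to 0.914% under random shifts of 50 kb to 500 kb and to 0.663% when peak-free stretches were left out of the placement. Without the replicate 2 peaks within 1 Mb of stretches that lack peaks of both replicates, 91.2% were shared. The percentage of shared sites with a neighbour within 10 kb was 39.0% in the main set (15.9% by chance), 42.1% from the whole list of replicate 2 (17.4%) and 59.0% from that of replicate 1 (36.4%), so the excess over chance fell from 2.45-fold to 1.62-fold with replicate 1 alone. Of 4 density alternatives 2 moved, those of chromosomes 11 and X computed from replicate 1 alone, 30.8 and 10.1 peaks per occupied Mb, because that list is longer. The order of the chromosomes changed too. In replicate 1 alone chromosome 20 had 30.7, close to chromosome 11. Chromosome 2 had 26.0 there, below chromosomes 17 (28.3) and 12 (26.4). The overlap needs both replicates, so neither could be left out of it. The 500 bp limit, the settings that use peak-free stretches and all spacing, window and chromosome alternatives were chosen after seeing the data. Other choices for site annotation, motifs and gene lists were not run.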

Other observations

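The grouping of FOXA2 sites extended to longer runs. Taking sites no more than 10 kb apart as a run, 99 runs held 5 or more shared sites and 547 sites in all, against 1.31 such runs on average and 7 at most in 1000 random placements (one-sided permutation p = 0.001). Random shifts of 50 kb to 500 kb gave 13.5 on average and 27 at most (one-sided permutation p = 0.001). The longest run was on chromosome 11 from 20016870 to 20053492 and held 10 sites in 36.6 kb, a length that random shifts exceeded (14 at most), so the excess lies in the number of runs. The next were on chromosome 1 from 234736451 to 234779180 with 9 sites, on chromosome 11 from 113948557 to 113980392 with 8 and a median mean score of 35, and on chromosome 2 from 216529731 to 216558517 with 8. These regions were chosen after their values were seen.

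In the tests that follow, the neighbourhood of replicate 1-only peaks and the trend within chromosomes had their predictions written before the result was seen, and the other tests were chosen afterwards. Apart from a possible difference in whole-chromosome copy number, no biological explanation was tested, since the replicates are not different groups of the design.

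The first pattern is the 39604 peaks of replicate 1 that replicate 2 lacks. For replicate 1 peaks, the tags expected in replicate 2 were taken from the replicate 1 score, a score ratio and the depth of replicate 2. That ratio, replicate 2 to replicate 1, was 0.714, as seen in the 10% with the highest scores. Over all shared sites the median ratio of replicate 1 to replicate 2 was 1.20, so the expected tags depend on the ratio chosen. Among the 12015 peaks with 20 or more tags expected, 5.052% had no replicate 2 peak within 500 bp (95% Wilson interval 4.67% to 5.46%). Poisson counting gave 0.056%. The shortfall shrank with strength. With 20 to 30 tags expected, 89.6% had a replicate 2 peak within 500 bp, with 30 to 40 98.1%, and with 40 or more 99.7%. Replicate 1 scores may be raised by their own selection, which was not modelled, and single libraries may differ by more than counting error. The test therefore cannot tell whether lower depth alone accounts for these stronger peaks. The weaker peaks were judged by overlap of at least 1 bp instead of the 500 bp limit. Of the 16465 peaks with 10 to 20 tags expected, 53.08% were shared against 80.7% under Poisson counting (92.3% at a threshold of 8 tags instead of 10). With 500 bp allowed, 49.5% of those with 10 to 15 tags and 75.5% of those with 15 to 20 had a counterpart. Poisson counting gave 74.3% and 97.4%. This shortfall may in part come from replicate 1 scores raised by their own selection, which was not modelled. Among the 35469 peaks with fewer expected, 12.51% were shared against 15.8%, but this hides 4.18% against 1.68% below 5 tags and 14.0% against 18.3% from 5 to 10, and a threshold of 8 tags would put the Poisson values at 8.50% and 38.9%, so the share due to depth stays open there. False calls placed without regard to shared sites are argued against as the whole source. Of the replicate 1-only peaks, 28.36% lay within 10 kb of a shared site, above the highest of 1000 random shifts, 20%. Of those more than 500 bp from any replicate 2 peak, 25.9% did so, without shifts of their own for comparison. False calls that gather around shared sites would give the same outcome, so the test cannot exclude them.

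The second pattern is the 46 strong replicate 2 peaks, with scores of at least 50, that had no replicate 1 peak within 500 bp. Of these, 34 lay within 1 Mb of a stretch of at least 1 Mb that lacks peaks of both replicates, against 49 of 1674 shared peaks of that score, but many of them lie side by side. Counted by windows of 1 Mb, 11 of 23 did so (47.83%, 95% Wilson interval 29.2% to 67.0%), against 31 of 953 windows with shared peaks of that score, or 3.25% (Fisher's exact test, two-sided, p = 2.2e-10). Repeat-rich sequence beside assembly gaps could account for these, but neither gaps nor repeats were annotated here, so it stays open. It leaves the other 12 windows, and the replicate 1 peak on chromosome 11 at 85195039 with its score of 570, without an explanation.

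The third pattern is the uneven ratio of replicate 1 to replicate 2 peaks over the chromosomes, which strong sites would not show if the calling threshold alone made it. Over 23 chromosomes, without Y, however, the ratio followed the median log2 score ratio of shared sites that scored 20 or more in both (Pearson's r = 0.807, two-sided permutation p = 1e-05, the smallest 100000 resamples can give; Spearman's rho = 0.76, permutation p = 7e-05; r = 0.78 without chromosomes 19 and 20, the farthest from the median). A difference in whole-chromosome copy number is one candidate explanation if the replicates came from separate cultures, which the labels do not say: neighbouring 5 Mb windows shared deviations from their chromosome's median only weakly (r = 0.09022 over 358 pairs, one-sided permutation p = 0.00799). That outcome met the bound set beforehand against copy number, and its reading was changed to undecided after the result was seen, because a trend this small within chromosomes does not forbid a cause acting between them. Copy number thus stays open, as does a difference in recovery by base composition, which was not tested.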
